A study of Mus musculus with 10 samples.

How the data were processed

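PolyA RNA from spermatogenic cells of mouse testes at postnatal day 18 was sequenced in 10 libraries, 5 labelled Ino80WT and 5 labelled Ino80cKO, the latter carrying a testis-specific deletion of Ino80 driven by Stra8-Cre. Per the labels' protocols, seminiferous tubules were digested with collagenase and trypsin, cells were passed through a mesh filter, RNA was extracted with TRIzol and a column kit, and stranded mRNA libraries were made with a Kapa kit. No sorting for a cell type is described, so Sertoli, Leydig, peritubular, endothelial, blood and immune cells can be present beside germ cells. The mice were of mixed background, per the labels.

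The deposited values are whole-number counts of reads per gene, 1 file per library, not normalized, per the file contents. The submitters' processing notes name TopHat2, HTSeq, DESeq2 and the mm10 build, without versions, and do not say which step used which. The gene annotation and the strand setting of the counting are not given in the sources used here. If counting ignored strand, reads of a gene and of an overlapping antisense gene cannot be told apart. HTSeq leaves out reads that align to several places, so genes with close copies are undercounted or uncertain. Each file held 23420 gene rows and 5 rows that name no gene (no feature, ambiguous, not unique and the like). The latter held 35.5% to 44.0% of all reads, with 18.4% to 26.3% not unique, and stayed out of library sizes and tests. No mitochondrially encoded gene was among the rows, so that list could not be tested. Gene counts per library ranged from 16750609 to 23700094. A floor of 3 counts is 0.127 to 0.179 CPM; it covers counting error only, since reads without molecular identifiers are not independent molecules.

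Gene symbols were matched to a RefSeq table of assembly GRCm38.p6, the same build as mm10, for chromosomes and positions, 21571 rows by current symbol and 1689 by an older symbol; 160 rows stayed unmatched and 23218 had a chromosome. List members were looked up under current and older symbols, and 680 of 710 were found. Gene names are printed as the files give them. Some single genes are not reported here, while totals still count them.

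Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on genotype (minimum count 10, minimum total 15), which left 15265, libraries were scaled by TMM factors, and a quasi-likelihood model with genotype as its only term was fitted with robust dispersions (glmQLFit and glmQLFTest). A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Log2 CPM values used a prior count of 2. Gene lists and chromosomes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over 25 lists and over the chromosomes. With the preset correlation 13 lists passed, 6 higher and 7 lower, and with the estimated one 0 did. Of the lists without a call at the preset correlation, none passed with the estimated one. The mean log2 CPM of each list per library was also compared between labels by an exact two-sided permutation test, adjusted over the lists. It takes libraries as its units and does not compare a list with other genes. The 7 lists lower by camera each had adjusted p = 0.02 in it, as did the p53, leukocyte and Y-linked lists. Exact two-sided permutation tests over all assignments of the 10 libraries can give no p below 0.00794.

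The model was first tested on simulated counts drawn from the means and library sizes of the 15265 genes, with 200 genes changed. Of 100 genes changed 2-fold (log2 of 1), 78% were called, and of 100 changed by 0.5 on the log2 scale 40% were, none in the wrong direction. Of the calls, 5.6% were of unchanged genes. These shares hold for a simulation with few changed genes. With many changed genes, as in the real counts, the threshold on p is less strict and smaller changes can pass.

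No pair of libraries was a duplicate: the lowest chi-square per degree of freedom between libraries was 8.93. Pearson correlations of log2 CPM were 0.973 to 0.991 within Ino80WT and 0.982 to 0.994 within Ino80cKO. The labels give no date, litter or sequencing batch. Replicate numbers occur in both groups, but nothing says that they mark a shared litter or day.

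Before the data were examined, the groups, the tests, the 26 gene lists, the processing alternatives and the rule for named genes were fixed. The rule names Ino80, the 12 genes with the largest rise and the 12 with the largest fall (adjusted p below 0.05, average log2 CPM of at least 1, no overlap between groups, a symbol other than Gm or LOC with a number, one ending in Rik or a similar provisional form), up to 4 members of each list with the smallest adjusted p (up to 2 with the smallest p where none passes), and up to 3 genes of each sex chromosome. Alternatives were a block for the replicate number, DESeq2 1.42.0, limma-voom, RLE size factors, library totals as the only scaling, no filter or a mean of at least 1 CPM, 1 surrogate variable (sva 3.50.0), an adjusted p below 0.01, a 2-fold limit and leaving out each library. After the data were seen, settings without Ino80WT 1 and 2 (richest in Rn45s), without Ino80WT 3 and Ino80cKO 5 (richest in Fos) and without the rows Rn45s and Lars2 were added, as were 5 gene lists named in the closing section. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.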

Results

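Transcript levels were measured by polyA RNA sequencing of spermatogenic cells from the testes of mice at postnatal day 18. At this age the first wave of germ cells has reached pachytene, the stage of meiotic prophase in which paired chromosomes recombine and the X and Y are silenced. INO80 is an ATP-dependent chromatin remodeller, and Stra8-Cre deletes floxed sequences in male germ cells. The series compared 5 libraries labelled Ino80WT with 5 labelled Ino80cKO, and its title ties INO80 to a polycomb subunit, so the comparison asks which transcripts depend on INO80 in these cells. Counts assigned to genes ranged from 16750609 to 23700094 per library, which puts a floor of 3 counts between 0.127 and 0.179 CPM (counts scaled to library size), a limit that covers counting error only. The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries, which may be partly technical. Unless another test is named, p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 5 libraries per group, and errors are SE for log2 fold changes (Ino80cKO over Ino80WT) and SD for CPM.

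The gene-level count of Ino80 (mm10, chromosome 2, positions 119373042 to 119478685) did not differ between the labels. It was 95 ± 12.6 CPM in Ino80WT and 96.1 ± 1.37 CPM in Ino80cKO, a log2 fold change of 0.02 ± 0.09 (adjusted p = 0.889), with a 95% interval of the fold from 0.879 to 1.16. An exact two-sided permutation test of CPM over all assignments of the libraries gave p = 0.833. Single libraries ranged from 75.8 to 110.1 CPM in Ino80WT and from 94.5 to 97.5 CPM in Ino80cKO. Which part of the gene is deleted is not given in the sources used here, and reads from the remaining exons still count towards the gene, so this count neither checks the labels nor measures the deletion. All directions below rest on the labels alone.

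Libraries labelled Ino80cKO had lower levels of spermatocyte transcripts and higher levels of part of the transcripts of immune, somatic and sex-chromosome genes. Of 15265 genes tested, 7013 changed, 2793 of them higher and 4220 lower in Ino80cKO. Changes of at least 2-fold were mostly falls, with 1179 genes lower and 113 higher (890 and 213 under library totals). Among genes meeting the rule for naming, which leaves out provisional symbols such as 1700080O16Rik, the 12 with the largest rises were H2-Aa, Iigp1, H2-Eb1, Cd74, Cd209c, Rtp4, Ccnb3, Zfy2, Srgap1, Irf7, Tgfbi and Gbp6. H2-Aa, H2-Eb1 and Cd74 act in MHC class II antigen presentation, and Iigp1, Rtp4, Irf7 and Gbp6 are induced by interferon. Cd74 rose from 6.55 ± 3.35 to 24.1 ± 9.04 CPM (3.73-fold, log2 1.90 ± 0.36, adjusted p = 0.00128), and Cd209c, a C-type lectin, from 53.9 ± 14.5 to 192 ± 53.8 CPM (3.56-fold). Ccnb3, the X-linked cyclin B3 of early meiotic prophase, rose from 49.8 ± 12.1 to 138 ± 27.9 CPM (2.76-fold, log2 1.47 ± 0.18, adjusted p = 9.01e-05). The 12 with the largest falls were Ceacam20, Pnmal1, Tcp10b, Il33, Myl10, Efcab8, Efcab10, Spata18, Adam5, Riiad1, Gpr62 and Prss43. Adam5, of the sperm surface ADAM family, fell from 466 ± 155 to 128 ± 34.2 CPM (3.63-fold lower, log2 -1.86 ± 0.24, adjusted p = 0.00012). Pnmal1 fell from 48.8 ± 6.79 to 12.1 ± 2.07 CPM (4.03-fold lower). Tcp10b has close copies, so its count is uncertain.

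The groups did not overlap in CPM for 4879 genes (32.0% of those tested, against 0.794% by chance). The first principal component held 60.8% of the variance and separated the labels. The balance of rises and falls depended on the scaling. Scaling by library totals alone moved the median log2 fold change of all tested genes from 0.02 to 0.19, and 34.9% of changed genes were then lower, against 60.2% here, with 5484 higher and 2937 lower. Without Ino80WT libraries 1 and 2, which held the most counts of the ribosomal RNA precursor Rn45s (7.08% and 4.67% of gene counts), 190 genes were higher by at least 2-fold.

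**Figure D1:**
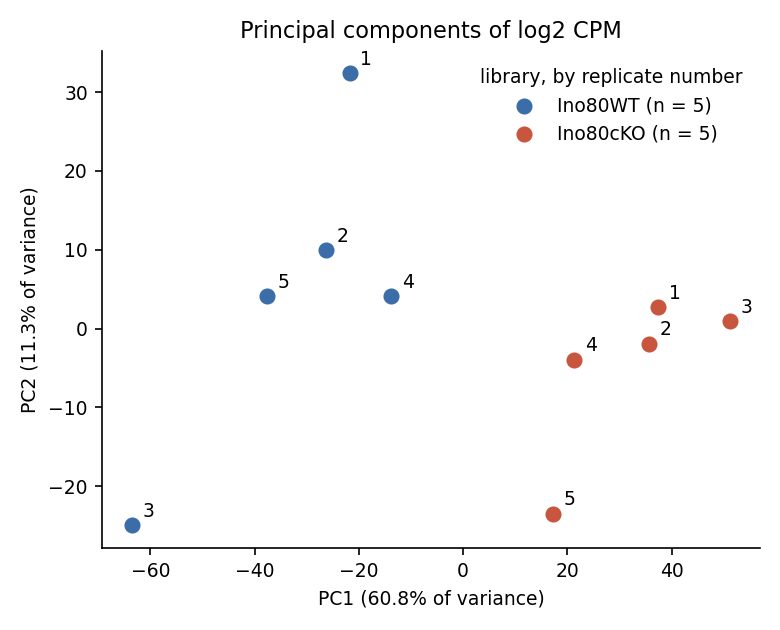
Principal components of log2 CPM over the 15265 tested genes, with component 1 (60.8% of the variance) on the horizontal and component 2 (11.3%) on the vertical axis; each point is a library, numbered by replicate. All 5 Ino80cKO libraries lie right of all 5 Ino80WT libraries, and Ino80WT 1, Ino80WT 3 and Ino80cKO 5 stand apart from the rest of their groups on the vertical axis.

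Transcripts of pachytene and later spermatocytes fell together. Of 47 tested members of this list, 41 were lower, 1 was higher and 5 did not pass, with the same counts of 41 and 1 adjusted over the list alone, and the median log2 fold change was -1.28. Cks2, a subunit of cyclin-dependent kinase complexes needed in meiosis, fell from 182 ± 13.5 to 91.6 ± 9.29 CPM (1.98-fold lower, log2 -0.99 ± 0.09, adjusted p = 3.35e-05). Cetn1, a centrin of germ cells, fell from 166 ± 40.1 to 52.5 ± 11.2 CPM (3.16-fold lower), and the transcription factors Crem and Tcfl5 fell by 1.17 and 1.14 on the log2 scale. Of 40 listed spermatid genes, 12 passed the count filter. Among these 12, 7 were lower and none higher (7 adjusted over the list alone), with a median of -1.08. They included Dkkl1 (3.13-fold lower), Catsper2, a sperm calcium channel subunit (2.86-fold lower), and Actl7b (3.46-fold lower). At this age the first wave has reached pachytene, so these transcripts need not come from spermatids. The gene-set test camera placed both lists lower than other genes (adjusted p = 5.77e-18 and 0.00383), and adjusted p = 0.407 and 0.501 with an estimated correlation. Ino80WT 3 held the highest mean level of the pachytene list, 7.18 log2 CPM, with the other Ino80WT libraries at 6.36 to 6.77 and Ino80cKO at 5.25 to 5.87.

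The piRNA pathway, which silences transposons in male germ cells, had 19 of 26 members lower, none higher and 7 that did not pass (19 adjusted over the list alone), with a median of -0.77. Its level was highest in Ino80WT 3 (6.77 log2 CPM) and lowest in Ino80cKO 3 (5.51), as for the pachytene list. The RNA helicase Ddx4 fell from 824 ± 105 to 436 ± 46.4 CPM (1.89-fold lower, log2 -0.92 ± 0.10, adjusted p = 6.95e-05), Tdrd9 fell 1.88-fold, Asz1 1.65-fold and Mael 2.14-fold. This list shares Piwil1 and Mybl1 with the pachytene list. Camera gave adjusted p = 1.57e-09, and adjusted p = 0.407 with an estimated correlation.

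Part of the genes of the meiotic chromosome axis and of recombination were also lower. In the list of synaptonemal complex, cohesin and axis genes, 12 of 18 were lower and none higher (12 adjusted over the list alone), with a median of -0.49. Syce1, of the central element of the synaptonemal complex, fell from 214 ± 33.0 to 99.8 ± 12.6 CPM (2.15-fold lower), Syce3 fell 1.97-fold, and Hormad2 and Tex12 fell 1.57-fold and 1.48-fold. Of 48 recombination and double-strand break repair genes, 23 were lower, 1 higher and 24 did not pass (24 lower and 1 higher adjusted over the list alone), with a median of -0.23. Cntd1, a crossover regulator, fell from 272 ± 25.5 to 108 ± 13.6 CPM (2.51-fold lower, log2 -1.33 ± 0.10, adjusted p = 2.99e-05). Psmc3ip, a partner of the DMC1 recombinase, fell 2.23-fold, and Spo11, which makes the meiotic breaks, and the crossover factor Mlh3 fell 2.20-fold and 1.98-fold. Dmc1 itself had a log2 fold change of -0.07 that did not pass, a value singled out after it was seen. Camera gave adjusted p = 0.00147 and 0.000177, and adjusted p = 0.501 and 0.407 with an estimated correlation. With library totals as the scaling, 18 recombination genes were lower and 9 higher, with a median of -0.05. Over the alternative settings the median of the synaptonemal complex, cohesin and axis list ran from -0.575 to -0.31.

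Among genes of meiotic entry and early prophase, 11 of 19 were lower and 2 higher (11 and 2 adjusted over the list alone), with a median of -0.28, against 7 lower, 3 higher and a median of -0.10 under library totals. Besides Spo11 and Mael, Gml fell 1.79-fold and the germ cell surface protein Tex101 1.72-fold. Camera gave adjusted p = 0.021, and adjusted p = 0.511 with an estimated correlation. The spermatogonial lists did not pass camera. In the list of undifferentiated spermatogonia, 5 of 24 were higher and 1 lower (0 higher and 1 lower adjusted over the list alone), with a median of 0.24 and adjusted p = 0.0656. Id4, which marks spermatogonial stem cells but is also transcribed in spermatocytes, fell from 78.1 ± 11.4 to 38.3 ± 6.57 CPM (2.04-fold lower), and Etv5, Uchl1 and Foxo1 rose 1.40-fold, 1.24-fold and 1.17-fold. Without Ino80WT replicate 5 none of this list was higher. In the list of differentiating spermatogonia, 3 of 15 were lower and 2 higher (3 and 1 adjusted over the list alone), and the median (0.10) and mean (-0.02) differed in sign. By library totals 6 were higher and 1 lower (median 0.27), and leaving out 1 library gave 1 to 4 higher (4 without Ino80WT replicate 1). Dmrtb1, which controls the entry into meiosis, fell from 180 ± 77.2 to 73.7 ± 16.6 CPM (2.44-fold lower), Uhrf1 and Sohlh2 fell 1.28-fold and 1.22-fold, and Ccnd2 rose 1.38-fold. Camera gave adjusted p = 0.539.

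**Figure D2:**
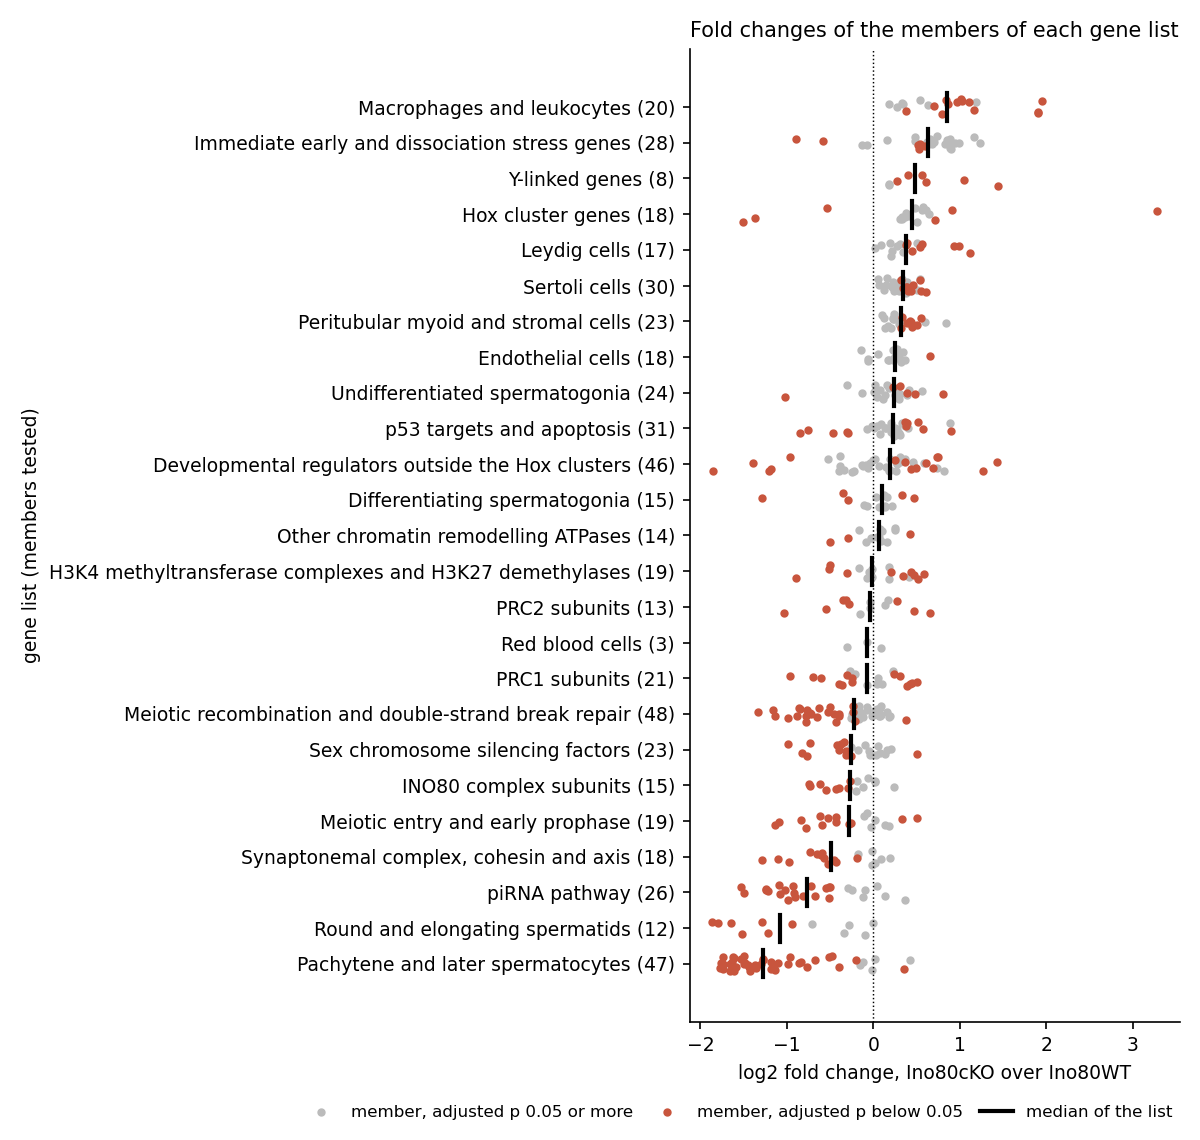
Log2 fold change (Ino80cKO over Ino80WT, horizontal axis) of the tested members of 25 gene lists (vertical axis, number tested in parentheses); each point is a gene, red where its adjusted p was below 0.05, and the black bar is the list's median. Medians run from -1.28 for pachytene and later spermatocytes to 0.85 for macrophages and leukocytes.

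Subunits of the INO80 complex were in part lower. Of 15 members, which include Ino80 itself, 8 were lower and none higher (8 adjusted over the list alone), with a median of -0.27. Ino80 was not among the 8. The list's level was highest in Ino80WT 3 (6.32 log2 CPM) and lowest in Ino80cKO 3 (5.76), as was that of the pachytene list. Ino80c fell from 87.7 ± 12.5 to 52.9 ± 3.45 CPM (1.66-fold lower, log2 -0.73 ± 0.10, adjusted p = 0.000129). The AAA+ ATPase Ruvbl2 fell 1.67-fold, the deubiquitinase Uchl5 1.54-fold and the actin-related protein Actr5 1.46-fold. Ruvbl2 and Actr5 are also transcribed outside germ cells, and Ruvbl2 serves other complexes. Camera gave adjusted p = 0.0166, and adjusted p = 0.511 with an estimated correlation. With library totals as the scaling the median was -0.09 and adjusted p = 0.0601.

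Polycomb subunits moved in both directions. Of 13 PRC2 subunits, 5 were lower and 3 higher (6 and 4 adjusted over the list alone), with a median of -0.04 and camera adjusted p = 0.539. Phf1, an accessory subunit that binds methylated H3K36, fell from 119 ± 22 to 58.1 ± 8.63 CPM (2.05-fold lower, log2 -1.04 ± 0.14, adjusted p = 0.000126). Mtf2 fell 1.46-fold, the methyltransferase Ezh2 1.28-fold and the core subunit Eed 1.24-fold. Of 21 PRC1 subunits, 8 were lower and 6 higher (9 and 6 adjusted over the list alone), with a median of -0.08 and camera adjusted p = 0.813. Pcgf6 fell from 138 ± 17.5 to 70.5 ± 10.9 CPM (1.95-fold lower), Cbx7 and Pcgf5 fell 1.62-fold and 1.52-fold, and the X-linked, germline-specific Scml2 rose from 203 ± 17.9 to 287 ± 27.7 CPM (1.41-fold higher). Under library totals, 4 PRC2 genes were higher and 3 lower (median 0.14), and 9 PRC1 genes were higher and 4 lower (median 0.09). Phf1, Mtf2, Ezh2, Pcgf6, Pcgf5 and Cbx7 were each highest in Ino80WT 3 and lowest in Ino80cKO 3, as was the pachytene list. Eed was lowest in Ino80cKO 3 but highest in Ino80WT 5.

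The list of H3K4 methyltransferase complexes and H3K27 demethylases also holds H3K4 demethylases of the Kdm5 family. Of its 19 tested members, 6 were higher and 4 lower (7 and 4 adjusted over the list alone), with a median of -0.02, a mean of 0.04 and camera adjusted p = 0.539. Psip1 fell 1.86-fold from 828 ± 119 CPM, Ash2l 1.42-fold and the H3K4 demethylase Kdm5b 1.41-fold, while its X-linked relative Kdm5c rose 1.5-fold. Of 14 other remodelling ATPases, Atrx, also X-linked, rose 1.34-fold, and Ep400 and Chd5 were 1.42-fold and 1.23-fold lower (0 higher and 0 lower adjusted over the list alone), with a median of 0.07 and camera adjusted p = 0.447. The calls of Ep400 (adjusted p = 0.0274) and Chd5 (adjusted p = 0.0477) were lost in 8 and 18 of the 21 alternative settings. Scaled by library totals, 9 of the 14 were higher and none lower.

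Hox genes, classical polycomb targets, were at low levels, and 18 of 39 passed the count filter. Of these, 3 were higher and 3 lower (3 and 3 adjusted over the list alone), with a median of 0.45 and camera adjusted p = 0.131, and 5 were higher without Ino80WT replicate 4, as well as without Ino80WT 1 and 2. The list's mean level was higher in Ino80cKO (exact permutation test over libraries, adjusted p = 0.046). Hoxa4, transcribed in germ cells, fell from 24.8 ± 7.05 to 8.74 ± 2.45 CPM (2.84-fold lower, log2 -1.51 ± 0.22, adjusted p = 0.000282), Hoxa3 fell 2.58-fold and Hoxd8 1.45-fold. Hoxd13 was at 0.102 ± 0.078 CPM in Ino80WT, 10 counts over all 5 libraries, and at 1.07 ± 0.52 CPM in Ino80cKO, 116 counts (adjusted p = 0.0003). Among 46 tested developmental regulators outside the Hox clusters, 10 were higher and 5 lower (10 and 5 adjusted over the list alone), with a median of 0.19 and camera adjusted p = 0.13. En2, Nkx6-2 and Irx2 fell 3.62-fold, 2.62-fold and 2.31-fold, and Lhx2 rose 1.66-fold to 6.96 ± 1.02 CPM.

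Sex-chromosome genes were higher as a group. Of 597 X-linked genes tested, 294 were higher and 1 lower, with a median log2 fold change of 0.34 (442 higher and a median of 0.51 under library totals), and of 8 Y-linked genes 6 were higher and none lower (6 adjusted over the list alone), with a median of 0.48. Over the 19 autosomes, 17.0% of 14574 genes were higher and 28.8% lower, and chromosome medians lay between -0.04 and 0.05. Camera over chromosomes gave adjusted p = 2.04e-17 for X and 0.00425 for Y, with 0.925 the lowest among autosomes. With an estimated correlation X and Y each had adjusted p = 0.916. Rises of at least 2-fold were seen for 10 of the 597 genes on X and 2 of the 8 on Y, against 99 of the 14574 autosomal genes.

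**Figure D3:**
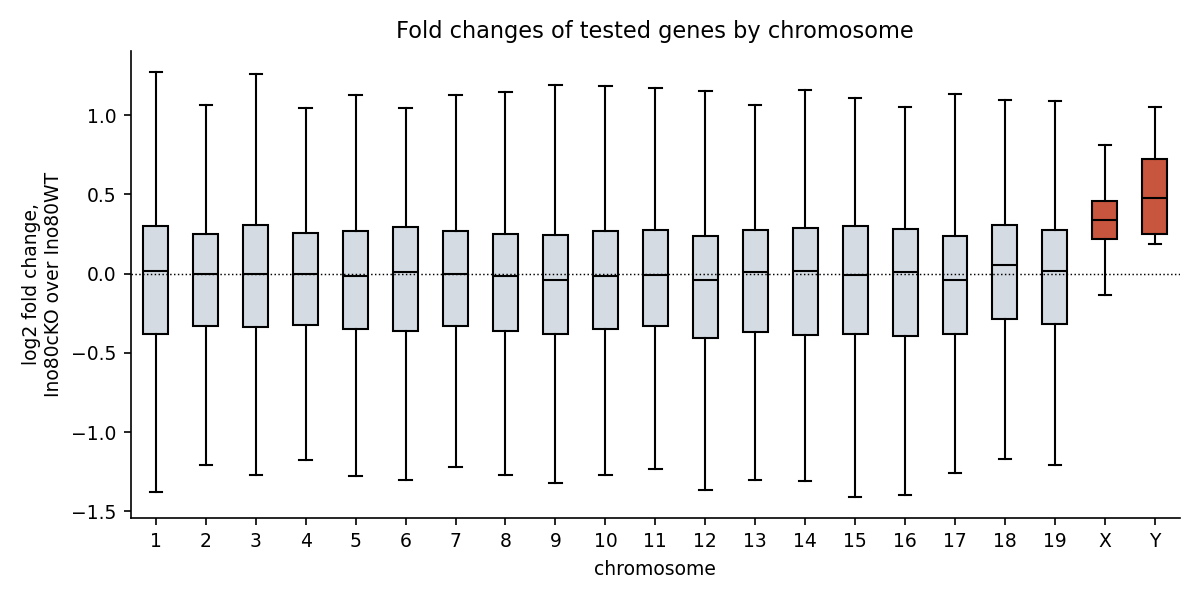
Log2 fold change (Ino80cKO over Ino80WT, vertical axis) of tested genes by chromosome; boxes span the quartiles with the median as a line, whiskers reach the last value within 1.5 box lengths, and points beyond are not drawn. The X (median 0.34) and Y (median 0.48) boxes lie above 0, while autosomal medians lie between -0.04 and 0.05.

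On the X, the genes with the smallest adjusted p were 1700080O16Rik, Gm5934 and Otud5. 1700080O16Rik (positions 51968693 to 51973502) rose from 4.90 ± 1.41 to 24.1 ± 4.81 CPM (4.93-fold, log2 2.30 ± 0.19, adjusted p = 2.99e-05). Gm5934 was at 0.129 ± 0.108 CPM in Ino80WT, 12 counts in all, and 3.52 ± 1.15 CPM in Ino80cKO, 382 counts (adjusted p = 3.91e-05). Otud5, a deubiquitinase, rose 1.48-fold from 59.9 ± 1.51 CPM. On the Y, the zinc-finger gene Zfy2 (positions 2106175 to 2170409) rose from 5.28 ± 1.93 to 14.4 ± 3.25 CPM (2.71-fold, log2 1.44 ± 0.25, adjusted p = 0.000715), its near-copy Zfy1 from 6.08 ± 1.77 to 12.6 ± 2.56 CPM (2.07-fold), Kdm5d 1.48-fold and Uba1y 1.31-fold. Reads that aligned to several places were not counted, so the level of Zfy1, Zfy2 and multicopy X genes such as Gm5934 is uncertain. Of 23 factors of sex chromosome silencing, 11 were lower and 1, Scml2, was higher (12 and 1 adjusted over the list alone), with a median of -0.26 and camera adjusted p = 0.069. Under library totals 6 were lower and 3 higher, with a median of -0.08. The list's mean level was lower in Ino80cKO (exact permutation test over libraries, adjusted p = 0.046). It was highest in Ino80WT 3 (7.46 log2 CPM) and lowest in Ino80cKO 3 (7.02), as was that of the pachytene list. Mdc1, which spreads the DNA damage signal over the X and Y, fell from 753 ± 120 to 454 ± 42.7 CPM (1.66-fold lower), Eif2c4 (Ago4) fell 1.98-fold and Topbp1 1.31-fold.

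Part of the markers of leukocytes, Sertoli, Leydig and peritubular cells were higher, with the highest median in leukocyte markers. Of 20 genes of macrophages and leukocytes, 13 were higher and none lower (15 and 0 adjusted over the list alone), with a median of 0.85. Ctss, a lysosomal protease, rose from 3.14 ± 0.51 to 7 ± 1.09 CPM (2.23-fold), and Tyrobp, Laptm5 and the macrophage receptor Csf1r rose 2.16-fold, 1.96-fold and 1.73-fold. The Sertoli list had 10 of 30 higher (8 adjusted over the list alone, median 0.34), with Gata4 rising from 69 ± 6.81 to 105 ± 11.6 CPM (1.53-fold), Fshr 1.46-fold, Sox9 1.37-fold and Vim 1.26-fold. The Leydig list had 8 of 17 higher (8 adjusted over the list alone, median 0.38), with Lhcgr at 2.16-fold, Hsd3b6 at 1.91-fold, Pdgfra at 1.48-fold and Srd5a1 at 1.30-fold. The peritubular and stromal list had 9 of 23 higher (9 adjusted over the list alone, median 0.32), with Tcf21 and Col1a1 each at 1.36-fold and Col1a2 at 1.31-fold. None of these 3 lists had a member lower. Camera gave adjusted p = 1.71e-06 for leukocytes, 0.000177 for Sertoli, 0.00248 for Leydig and 0.00107 for peritubular genes, and adjusted p = 0.407 for leukocytes and 0.501 for the others with an estimated correlation. The exact permutation test of list levels over libraries gave adjusted p = 0.02 for leukocytes and 0.046 for Sertoli genes. For Leydig and for peritubular genes it gave adjusted p = 0.059, which did not pass.

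Of 18 endothelial genes only Robo4 rose (1.58-fold; 1 adjusted over the list alone), with a median of 0.25 and camera adjusted p = 0.0516. The 3 red blood cell genes tested did not pass (0 and 0 adjusted over the list alone); Alas2 had a log2 fold change of -0.30 ± 0.35, and the list's median of -0.07 differed in sign from camera's direction (adjusted p = 0.893). Counts of higher Sertoli genes ranged from 6 without Ino80WT replicate 5 to 17 without Ino80cKO replicate 5, and those of higher peritubular genes from 4 without Ino80cKO replicate 1 to 14 without Ino80cKO replicate 5. Without Ino80WT replicate 3, 5 Leydig genes were higher. Scaled by library totals, 16 leukocyte, 21 Sertoli, 12 Leydig, 18 peritubular and 6 endothelial genes were higher, and without Ino80cKO replicate 5 there were 3 higher endothelial genes.

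**Figure D4:**
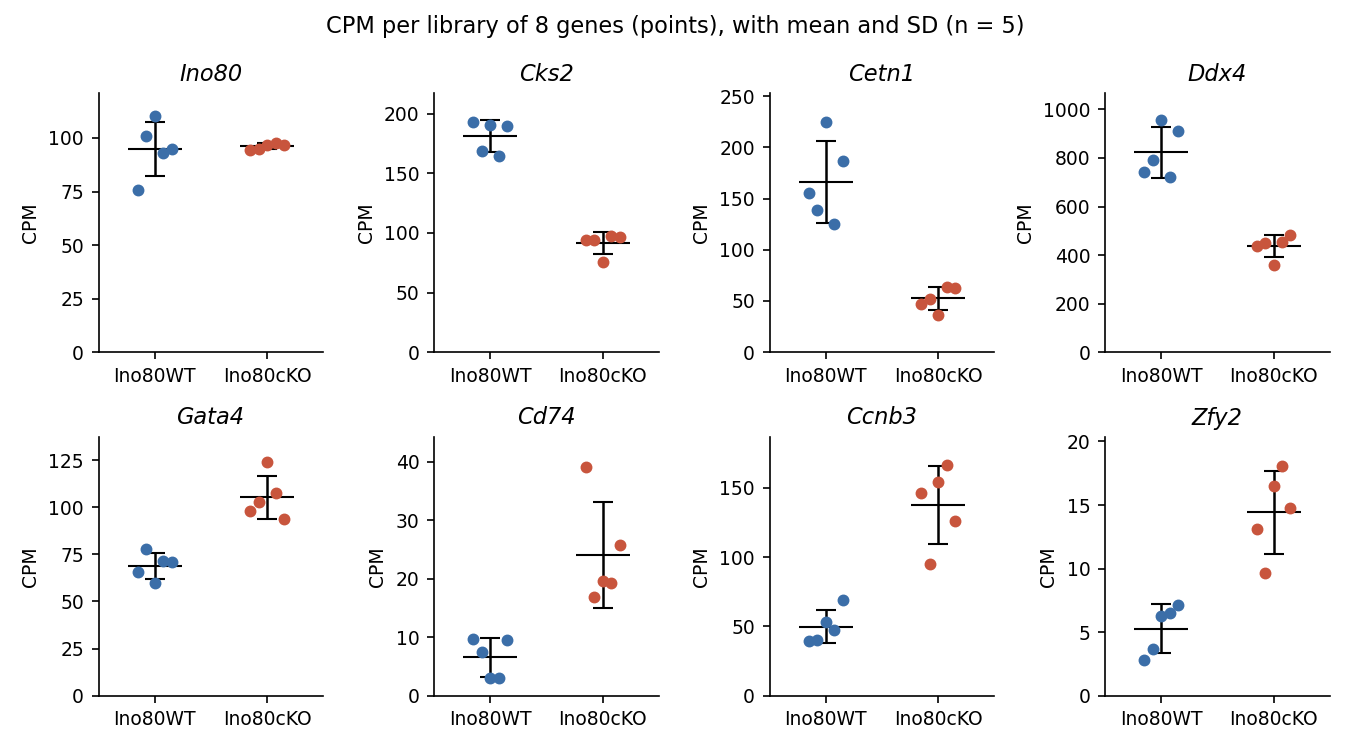
CPM (vertical axes, from 0) of 8 genes in each of the 5 Ino80WT (blue) and 5 Ino80cKO (red) libraries; points are libraries, the wide bar is the mean and the error bar the SD. Ino80 is at 95 and 96.1 CPM, Cks2, Cetn1 and Ddx4 are lower and Gata4, Cd74, Ccnb3 and Zfy2 higher in Ino80cKO, and for these 7 genes the groups do not overlap.

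Genes of p53 signalling and apoptosis moved both ways, with 6 of 31 higher and 5 lower (6 and 4 adjusted over the list alone), a median of 0.23 and camera adjusted p = 0.0477, and adjusted p = 0.407 with an estimated correlation. Trp53 rose from 45.1 ± 4.95 to 59.2 ± 5.56 CPM (1.31-fold), the proapoptotic Bcl2l11 rose 1.49-fold, and Trp63 fell 1.80-fold. Camera's adjusted p for this list exceeded 0.05 in 6 of the 21 alternative settings. Scaled by library totals, 14 were higher and 3 lower, and without Ino80WT 1 and 2 the counts were 10 and 3. In the list of immediate early and dissociation stress genes, 4 of 28 were higher and 2 lower (2 and 2 adjusted over the list alone), with a median of 0.64 and camera adjusted p = 0.0638. The chaperone Hsp90aa1 fell from 4716 ± 750 to 2541 ± 274 CPM (1.86-fold lower) and the Hsp70 cochaperone Dnajb1 1.5-fold, while Hspb1 and Hspa1a rose 1.44-fold and 1.46-fold. Ino80WT 3 and Ino80cKO 5 stood apart in this list, at 5.68 and 6.38 log2 CPM against 4.03 to 4.84 in the others. Without both, 17 members were higher and 2 lower (camera adjusted p = 0.000412). Both were left out for their level of Fos, itself a member of this list. Their removal narrows the list's spread within the groups, so these values are no support for a rise. With all libraries, the exact permutation test of the list's level gave adjusted p = 0.46. Leaving out 1 library gave 2 to 10 higher members, with 10 and a median of 1.10 without Ino80WT replicate 3 and a median of 0.03 without Ino80cKO replicate 5.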

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

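In 292 groups of 5 values (named genes, list levels and library measures in each label), the gap of 1 library to its nearest neighbour, divided by the range of the group, exceeded Dixon's critical value of 0.71 in 24, where chance gives about 14.6. The tests in the paragraphs that weigh explanations were chosen after the results were seen, although scaling by library totals was among the settings fixed before.

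Ino80WT 3 accounted for 8 of the 24. It was lowest in 4 somatic lists, at 6.09 log2 CPM for Sertoli genes (others 6.46 to 6.60, ratio 0.731), 3.12 for Leydig genes (ratio 0.815), 5.57 for peritubular genes (ratio 0.791) and 2.31 for endothelial genes (ratio 0.754). It was highest in immediate early genes at 5.68 (others 4.03 to 4.33, ratio 0.821), in Dmrtb1 at 314 CPM (others 126 to 174, ratio 0.747), in Uhrf1 at 216 CPM (ratio 0.801) and in Pcgf5 at 150 CPM (ratio 0.893). Ino80cKO 5 was highest in immediate early genes at 6.38 (others 4.40 to 4.84, ratio 0.777) and in undifferentiated spermatogonia at 3.76 (ratio 0.712), and lowest in Csf1r at 9.84 CPM (ratio 0.713).

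Ino80WT 1 was lowest in the list of H3K4 methyltransferase complexes and H3K27 demethylases at 6.85 log2 CPM (others 7.12 to 7.17, ratio 0.836) and in other remodelling ATPases at 7.18 (ratio 0.726), and highest in Tgfbi at 21.9 CPM (ratio 0.843), Syce3 at 39.6 CPM (ratio 0.751) and Hspb1 at 54.5 CPM (ratio 0.734). Ino80cKO 3 was lowest in Actr5 at 19 CPM (ratio 0.832), Cntd1 at 84.9 CPM (ratio 0.748) and Cks2 at 75.3 CPM (ratio 0.843), and highest in Sox9 at 198 CPM (ratio 0.786). Ino80cKO 1 was highest in H2-Eb1 at 14.5 CPM (others 4.72 to 7.12, ratio 0.755), Ino80cKO 2 was lowest in Otud5 at 78.3 CPM (ratio 0.716), and Ino80WT 4 was lowest in Hormad2 at 39.9 CPM (ratio 0.824). Ino80WT 2 stood apart in 1 group (ratio 0.904).

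The difference between the labels as a whole was set against other groupings of the libraries. Of 100 splits of the 10 libraries into groups of 5, 1, the real one, called as many as 7013 genes, and the highest of the others called 1. Every other split mixed both labels on each side, so the difference between labels widened the spread within its groups. Few calls were therefore likely in advance. The splits show that the main division of the libraries follows the labels. They cannot tell genotype from any other difference that goes with the label.

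The fall of transcripts of pachytene and later spermatocytes was weighed against library scaling, libraries rich in Rn45s and the make-up of the sampled cells. Library totals as the only scaling left the list's median at -1.10 and leaving out Ino80WT 1 and 2 left it at -1.27, against -1.28, so neither accounts for the fall. A lower share of later spermatocytes among the sampled cells stays open and may account for part of it: across 15218 genes outside the list, which are not independent replicates, the slope on the list's level among the Ino80WT libraries correlated with the fold change between labels at r = -0.578 (rho -0.573), and the slope among Ino80cKO libraries at -0.589 (rho -0.572). An exact one-sided permutation test of the list's level among the 5 libraries of a label gave p = 0.0417 and 0.025, and without Ino80WT 3 the Ino80WT value was weaker, at -0.355. Lower transcription per cell would give the same values and was not tested, and both an arrest before late pachytene and a direct dependence on INO80 remain hypotheses.

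The rise of sex-chromosome genes was weighed against the same change in make-up. X and Y genes are silent in pachytene cells, and a loss of these cells alone would raise the share of all other transcripts alike. The X median of 0.341 lies between the medians of the 4 somatic lists (0.248 to 0.375). Its bootstrap 95% interval (0.328 to 0.363) resampled genes and leaves out the spread between libraries. Over the alternative settings the X median ran from 0.296 to 0.513 and the Sertoli median from 0.269 to 0.51. The Y median of 0.479, over 8 genes, lay above all 4 somatic medians. Medians of undifferentiated (0.241) and differentiating spermatogonia (0.0983) lay below them. The first of these was close to the lowest somatic median, and the differences were not tested. Dmrtb1 and Uhrf1 of the differentiating list were highest in Ino80WT 3 and lowest in Ino80cKO 3, as was the pachytene list. Whether the rise was alike outside pachytene cells is therefore not settled. The place of the X among somatic lists does not settle the cause of its rise. Of all 605 X- and Y-linked genes, 3 (1700080O16Rik, Gm5934 and Ccnb3) exceeded the highest somatic median at a Benjamini-Hochberg adjusted one-sided p below 0.05, and 0 of 88 somatic list genes did (one-sided Fisher's exact test of the shares, p = 0.665). With 3 genes past the limit in all, that p is the smallest the test can give, so it decides nothing about an excess. An equal rise of the somatic size (at most 0.375) does not reach the log2 fold changes of these 3, which were 2.30, 4.74 and 1.47. They were picked as the most extreme of 605 genes, and Gm5934 rests on 12 counts in Ino80WT. Reads that aligned to several copies of Gm5934 were not counted, so its level is uncertain. Incomplete silencing of these 3 genes in spermatocytes may contribute to their rise and was not tested. The list of meiotic entry and early prophase was itself lower (11 of 19 genes, median -0.28, none above 0.50).

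The rise of leukocyte transcripts was weighed against a loss of spermatocytes that raises every other cell type alike, and against more leukocytes in the Ino80cKO preparations. The leukocyte median (0.851) exceeded that of the 88 other somatic genes (0.315) by 0.536. A permutation of gene labels gave p = 1e-05, the smallest it can give. It treats genes as independent, while their estimated correlation was 0.15 in the leukocyte list and 0.35 to 0.46 in the other somatic lists. This p leaves out the spread between libraries and does not decide the question. Over the alternative settings the leukocyte median ran from 0.743 to 1.02. Medians of the Sertoli, Leydig, peritubular and endothelial lists stayed at or below 0.556. An equal rise of that size falls short of the leukocyte median, but the gap was not tested against the spread between libraries. More leukocytes remain a candidate explanation. The 16 list members other than the MHC class II genes had a median of 0.816, with 10 higher, though at low levels, such as Csf1r at 6.46 CPM in Ino80WT and 11.2 CPM in Ino80cKO. Carry-over of interstitial cells at dissociation and infiltration of the testis would look alike here.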

How the results depend on the processing

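The 3 settings that remove libraries or rows by their Rn45s, Lars2 or Fos content were chosen after seeing the data. No list, chromosome or named gene that passed its threshold changed direction in any setting, while some values near 0, such as those of Ino80 and the polycomb lists, changed sign. The count of changed genes (7013) was 4340 at an adjusted p below 0.01 and 1292 with a 2-fold limit, both stricter by construction. It lay between 5936 and 7508 when each library was left out, and between 5493 and 8421 over all other settings at the same threshold. DESeq2 called 7648 genes, 6799 of them shared with edgeR, with 18 adjusted p-values of NA, and limma-voom 6999, of which 6874 were shared. Library totals alone gave 5484 higher genes against 2793, and the shift of all genes by that scaling is given in the report. Without a filter, 1 chromosome test passed in place of 2: Y had a median of 0.25 and adjusted p = 0.0669 (range 0.000322 to 0.0669 over settings), with the rarely detected Y genes then among those tested; the cause was not tested. The number of lists past camera's threshold was 11 to 17. The INO80 list lost its call under library totals, and the p53 list in 6 settings, while the lists of undifferentiated spermatogonia, sex chromosome silencing, endothelial and immediate early genes gained one in 7, 4, 10 and 8 settings. Of the values of named genes under alternatives, 2385 kept their side of the threshold and 48 lost the call. Shared replicate numbers showed no pairing: deviations of same-numbered libraries correlated at 0.20, 0.11, -0.47, -0.17 and -0.18, and 1 of 5 correlated best with its own number. With a replicate block, 5493 genes changed, 1921 higher and 3572 lower. Depth limits the genes with few counts, such as Hoxd13 and Gm5934, whose Ino80WT counts sum to 10 and 12.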

Other observations

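The gene lists here were chosen after the results were seen, so their counts describe these libraries and are no independent evidence. Interferon-induced genes rose as a group: of 53 tested, 42 were higher and 1 lower, with a median log2 fold change of 0.90 and camera adjusted p = 3.43e-16 (adjusted p = 0.163 with an estimated correlation). They included Iigp1 (log2 1.92), Oas1a (1.84), Rtp4 (1.80), Isg15 (1.65), Nlrc5 (1.36), a regulator of MHC class I genes, and Irf7 (1.31), while Parp12 was lower at -0.28. H2-K1 and H2-D1, classical MHC class I genes, had log2 fold changes of 0.19 and 0.38 that did not pass. Without 1 library at a time 35 to 43 members were higher. Which cells carried these transcripts was not tested.

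Axonemal and ciliary genes fell: of 65 tested, 59 were lower and 1 higher, with a median of -1.43 and camera adjusted p = 1.45e-22 (adjusted p = 0.163 with an estimated correlation). The tektins Tekt3 and Tekt4 had log2 fold changes of -1.68 and -1.64, the radial spoke gene Rsph1 -1.63 and Spag16 -1.77, which also stands in the pachytene list, as do Spag6 and Tekt1. Dnahc5 and Dnahc11, dynein heavy chains of motile cilia, had -0.15 and -0.20 and did not pass. Of 22 acrosome and sperm surface genes, 18 were lower and 1 higher (median -1.46, camera adjusted p = 2.92e-08, and 0.163 as adjusted p with an estimated correlation), among them Crisp2 (-1.77), Adam3 (-1.76) and Adam2 (-1.61); 7 of the 22 stand in fixed lists.

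Of 71 cytosolic ribosomal protein genes, 50 were lower and 2 higher, with a median of -0.36 and camera adjusted p = 2.92e-08 (adjusted p = 0.341 with an estimated correlation). With library totals as the scaling 29 were lower and the median was -0.19, and with processed copies throughout the genome their counts are uncertain. Rps24 fell by 0.77 on the log2 scale, and the X-linked Rpl10 rose by 0.27. Of 41 heat shock proteins and chaperones, 25 were lower and 3 higher (median -0.29, camera adjusted p = 2.2e-05, and 0.282 as adjusted p with an estimated correlation). The germ cell chaperones Hspa2 and Hspa4l were at -1.15 and -1.04, and Hspa5, of the endoplasmic reticulum, at 0.05. With library totals as the scaling 19 were lower and 9 higher.

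Of the 12 sex-chromosome genes that were higher by at least 2-fold, 10 are X-linked. Beside those named in the report these include 3830417A13Rik (1.55 ± 0.33 to 3.96 ± 0.737 CPM), Gm9 and Tsix, the antisense partner of Xist, at 0.349 ± 0.116 and 0.785 ± 0.216 CPM. Tsix overlaps Xist on the opposite strand, and the strand setting of the counting is not given, so its count may hold reads of Xist. The share of reads in no annotated feature was 17.6% ± 0.76 in Ino80WT and 17.6% ± 0.81 in Ino80cKO (exact permutation p = 0.937), and that of reads not uniquely aligned 21.9% ± 2.87 and 22.9% ± 1.32 (exact permutation p = 0.492).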
